A study of Mus musculus with 4 samples.

How the data were processed

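Single-cell RNA was measured with 10x Chromium 3' libraries in tumours of 4 littermate mice at postnatal day 20, 1 library per mouse. The mice carry Atoh1-cre:SmoM2, in which a constitutively active Smoothened is switched on in granule neuron precursors of the cerebellum and gives medulloblastoma of the Sonic hedgehog (SHH) type. Per the labels' protocols, tumours were dissociated with Accutase for 20 minutes, vital cells were sorted with 7-AAD, 10000 cells were loaded per lane, and the library of mouse 1 was sequenced in 2 rounds. A viability sort and the loss of fragile cells can set the shares of cell classes. Cell Ranger 2.0.2, Seurat and the genome build mm10 are named in the submitters' processing notes, which do not give the annotation release. The deposited values are UMI counts per gene and cell, not normalised, per the file headers and the whole numbers in the files.

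The files hold 5670 barcodes and 27998 genes. The series' design text states 4749 cells with a mean of 59566 ± 7821 reads per cell after quality filtering, with limits that are not given, so the files hold more barcodes than the study kept. Cells were kept with at least 500 detected genes and at most 10% of UMIs on mitochondrial genes. The gene minimum alone left 4620 barcodes and both filters left 4137. Scrublet, run per library with an expected rate of 2%, marked 15 cells (0.363%), a rate so low that the caller is taken not to have worked. Those 15 cells were removed, doublets otherwise remain, and 4122 cells were analysed. The libraries hold 3415171, 2573901, 1679285 and 3801197 UMIs for mice 1 to 4.

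Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (Python 3.11.15, numpy 2.4.6, scikit-learn 1.9.0): counts per 10000, log1p, 2000 highly variable genes, 30 principal components of scaled values, 15 neighbours and Leiden resolution 1, with no batch correction. Genes of all 18 gene lists, mitochondrial and ribosomal genes, Xist and Y-linked genes were kept out of the clustering. The study regressed the cell cycle out instead, per the series' design text, and that was run as an alternative. Clusters that led with markers of other cell types (322 cells) were clustered a second time. A cluster outside the granule lineage was named "like" a cell type by at least 3 markers of that type, fixed before the data were examined. Each had to be at least 1 log2 unit above the reference level and detected in 10% of the cluster's cells. All other clusters were taken as granule-lineage-like, with no minimum of granule markers. Of these, clusters were called differentiating where the median of the differentiating markers was at least 0.5 log2 units above the granule-lineage mean. That median also had to exceed the one of the progenitor markers. The rest were called progenitor-like by default, apart from the unnamed cluster, and no mature class was named. These limits, the second clustering and a gate for neutrophil-like cells were chosen after seeing the data. Of 165 marker genes, 162 are in the files. Trac, Trbc2 and Ighm are not, nor are the listed vesicle genes Vps28 and Chmp1b.

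The series has 1 group of 4 mice, so classes of cells were compared within the mice. UMI counts were summed per mouse and class and tested with edgeR 4.0.16 (quasi-likelihood fit and test, TMM normalisation, filterByExpr, R 4.3.3), with the mouse as a block, Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes carry a standard error worked back from the test, the absolute log2 fold change over the square root of its F statistic. It is not a spread over mice. Levels are CPM (counts scaled to a common library total), or UMIs per 10000, as mean ± SD over mice. Both classes of a mouse come from 1 animal and library, which pairs them, and the block takes up differences between libraries such as the sequencing rounds. The correlations of their deviations from the class means ran from 0.197 to 0.312 for the 2 granule-lineage classes and from -0.0417 to 0.245 over the other comparisons. A class needed at least 10 cells per mouse in at least 3 mice. Myeloid-like cells reached that in 2 mice, so both myeloid comparisons were run with at least 5 cells, a choice made after seeing the data, and the planned versions were not run. No vascular-like cluster was found and that comparison was not run.

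Counts of called genes cover held-out genes, those neither used for clustering nor cell type markers. The classes were drawn from the same cells, so these calls describe the classes and are no independent evidence for them. The 4 gene lists for extracellular vesicles (EV) hold 132 genes: the ESCRT machinery that buds vesicles into endosomes, tetraspanins and flotillins of vesicle membranes, regulators of release, and frequent cargo proteins. The other lists cover the SHH pathway, S phase, G2M phase, synapse, axon guidance and adhesion, glycolysis, antigen presentation, cytokines and chemokines, growth factors, matrix, immediate early and heat shock genes, lysosome, p53 targets and ribosomal proteins. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, repeated with an estimated correlation) and fry, adjusted over the lists of a comparison. The rule for named genes, fixed before the data were examined, took Cd9, Cd63, Cd81, Pdcd6ip, Sdcbp and Rab27a whatever their result. In each list it took up to 2 called members of the largest fold change with the same sign in every mouse and a mean log2 CPM of at least 5 (for oligodendrocyte-lineage-like cells and for myeloid-like against astroglia-like cells only the EV, growth factor, SHH and cytokine lists). In the other comparisons it took up to 3 higher and 3 lower held-out genes outside the lists. For the granule-lineage comparison it added Ptch1, Gli2, Mycn, Ccnd1, Ccnd2, Mki67 and Top2a. For genes named by fold change, the same direction in every mouse was thus a condition of being named and is no further support. Of 101 named symbols 100 match 1 gene of GENCODE vM21 (GRCm38), which gave the coordinates. A fold against a class without a UMI is a bound from a floor of 3 counts over the group. With 1 to 3 UMIs the ratio is given with a 95% counting interval, which covers counting error only.

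The share of cells with a UMI of Mki67 or Top2a was compared after each cell was thinned to 2000 UMIs, by an exact two-sided sign-flip test over mice. The edgeR, DESeq2 and camera steps were tested on simulated data with known changes for each comparison. There a small part of the genes changed, as many up as down, and both classes otherwise shared the same mean levels. The simulated data thus hold no shift of most genes, and their false rates do not cover errors of normalisation. Alternatives covered clustering resolution, clustering genes, cell cycle regression, cell filters, doublets, DESeq2 1.42.0, size factors, the low-count filter, the mouse block, depth, equal cell numbers and each mouse left out. Added after seeing the data were fits without cells low in Malat1, without Xist-positive cells of mice 2 and 4, with the unnamed cluster counted as progenitor-like, and with the astroglia-like cluster of the highest marker level alone, in mice with at least 5 of its cells.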

Results

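Transcripts were counted in single cells of SHH-type medulloblastomas from 4 Atoh1-cre:SmoM2 littermates. After filtering, 1364, 884, 704 and 1170 cells of mice 1 to 4 were analysed, with median depths of 2086.5, 2350.5, 1727 and 2564 UMIs per cell. The series title names an extracellular vesicle signature and its design text names tumour, immune and glial cells, so the comparisons ask which cell classes the tumours held and how their transcripts, vesicle genes among them, differed between classes.

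Granule-lineage-like cells made up most of every tumour. Progenitor-like cells, the granule-lineage-like clusters not called differentiating, were 81.0% ± 6.36 of cells (SD, n = 4 mice). Among them, clusters of 493 and 280 cells held 9.70 and 9.62 granule-lineage marker UMIs per 10000, with 18.6 and 12.9 of Malat1. The astroglia-like clusters held 11.2 to 11.9 granule-lineage marker UMIs per 10000. Differentiating granule-like cells, led by Cntn2, Stmn2, Tubb3 and Gap43, were 7.93% ± 2.52. They were named from differentiating markers, with no minimum of mature ones. Both shares moved with the clustering, as given below. Oligodendrocyte-lineage-like cells were 3.44% ± 1.23, of which 116 were precursor-like (led by Ptprz1, Cspg5 and Lhfpl3) and 23 oligodendrocyte-like (led by Cnp, Enpp6 and Mag), 21 of these in mouse 4. Astroglia-like cells were 3.11% ± 1.11, in 3 clusters. Aldoc was a leading gene of each, while Aqp4, Fabp7 and the metallothionein genes Mt1 and Mt2 led only part of them. The clusters, of 54, 51 and 31 cells, held 36.9, 29.7 and 121 astroglia marker UMIs per 10000, against 5.67 in progenitor-like cells. Most of the class thus lay well below its highest marker level. Myeloid-like cells were 0.900% ± 0.238, or 39 cells. Their cluster was led by Lyz2, a listed macrophage or monocyte marker, and Tyrobp, with the listed microglia markers C1qa, C1qb and Trem2. The class does not part microglia from macrophages. Their share in mouse 3, from 5 cells, was 0.710% with an exact Clopper-Pearson 95% interval of 0.231 to 1.65%. A cluster of 148 cells (3.47% ± 1.87) with a median of 985 UMIs stayed unnamed, because a B cell marker, Ebf1, but no granule marker stood among its leading genes. Yet it held 17.3 granule-lineage marker UMIs per 10000, against 9.62 to 17.6 in the progenitor-like clusters, and Top2a was also a leading gene. The lack of a name is thus no evidence against the granule lineage. There were 5 choroid-plexus-like and 3 neutrophil-like cells. None of the 4122 cells fell in a vascular-like, lymphocyte-like, ependymal-like or erythroid-like cluster. Types were given to clusters, so a few such cells could lie unseen inside others. The 3 neutrophil-like cells lay inside the myeloid-like cluster and were found by a separate gate. The lack of a cluster therefore sets no bound on a share. With 1 group of mice there is nothing to test shares against, and the viability sort can set them. The classes were also uneven inside the lineage, with 67.4% of 1 progenitor-like cluster from mouse 1 and 70.5% of another from mouse 3.

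**Figure D1:**
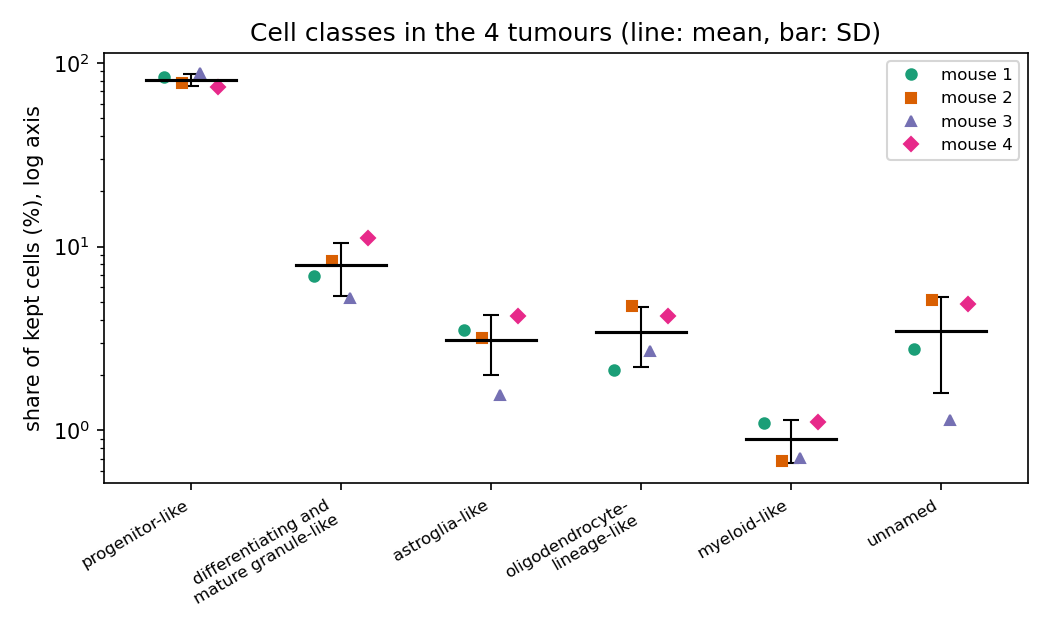
Share of kept cells in each cell class (percent, log axis) for the 4 mice, with the mean as a line and the SD as a bar. The class labelled differentiating and mature was named from differentiating markers, with no minimum of mature ones. Progenitor-like cells lie between 74.1 and 88.6% in the 4 mice and myeloid-like cells between 0.679 and 1.11%.

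Differentiating granule-like cells were compared with progenitor-like cells to ask which transcripts part the 2 classes of the tumour lineage. 2 SHH target genes were lower in the differentiating class, Ptch1, the SHH receptor and a direct target of the pathway, by -1.99 ± 0.18 log2 units (SE worked back from the edgeR test, n = 4 mice) and Ccnd1, a cyclin that drives cells into S phase, by -1.42 ± 0.13. Gli2, a transcription factor of the pathway, was at -2.23 ± 0.60, from 4 UMIs in the differentiating class, and lost its call in 5 of 20 alternatives. Slc17a6, a vesicular glutamate transporter (1.76 ± 0.24), and the guidance protein Sema6a (1.53 ± 0.26) were higher. The secreted factors moved in opposite directions, with Pdgfa, a ligand for oligodendrocyte precursors, at -2.34 ± 0.21 and the heparin-binding factor Ptn at 1.16 ± 0.12. Each of these genes changed in the same direction in 4 of 4 mice, with adjusted p in edgeR of 4.48e-25 for Ptch1, 6.71e-24 for Ccnd1, 0.00203 for Gli2, 7.24e-12 for Slc17a6, 9.8e-08 for Sema6a, 6.17e-27 for Pdgfa and 1.06e-20 for Ptn. For Slc17a6, Sema6a, Pdgfa and Ptn, which were not fixed beforehand, that agreement was a condition of being named. Ptch1 stood at 64.0 ± 35.2 CPM (SD) against 286 ± 46.4.

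Of 16 SHH pathway genes tested, 8 fell and 2 rose, and the list ranked below other genes (camera, adjusted p = 0.0157; adjusted p = 0.504 with an estimated correlation). The 2 that rose were Mycn (0.38 ± 0.13, edgeR adjusted p = 0.0242, higher in 4 of 4 mice) and Ccnd2 (0.27 ± 0.10, edgeR adjusted p = 0.0372, 3 of 4), both SHH targets in dividing precursors. Each lost its call in 8 of 22 alternatives. Cell cycle genes were lower: 33 of 42 S phase genes (camera adjusted p = 6.18e-17; adjusted p = 0.256 with an estimated correlation) and 50 of 52 G2M genes (4.5e-23; adjusted p = 0.242 with an estimated correlation), with none higher in either list. Mki67 and Top2a, which mark dividing cells, were at -2.50 ± 0.22 (edgeR adjusted p = 2.55e-28) and -2.26 ± 0.17 (4.54e-38), and Dtl and Clspn of S phase at -2.04 and -1.93. In the G2M list Cdca2 had 1 UMI against 358, a ratio of 0.0340 (95% counting interval 0.000860 to 0.191), and Bub1 3 against 371, a ratio of 0.0986 (0.0202 to 0.290). When S and G2M scores were regressed out before clustering, as the study states it did, the classes no longer differed in Mki67 (0.016) and Top2a (-0.07), Cdca2 was at 0.12, and Dtl (-0.12), Clspn (-0.31) and Bub1 (-0.29) were not called. That regression takes the cell cycle out of what parts the classes, so this loss was largely set in advance. It does not test the main difference. The classes then held other cells, and 359 of the 675 called held-out genes were also called in the main fit, with the same sign.

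Synapse genes rose in 14 of 27 tested, with none lower (camera adjusted p = 4.28e-13; adjusted p = 0.171 with an estimated correlation). In glycolysis Aldoa rose (1.22 ± 0.11, edgeR adjusted p = 1.34e-25) and Hk2, the first enzyme of the pathway, fell (-1.02 ± 0.24, 0.000253), within a list of 2 higher and 5 lower of 15. Immediate early genes fell in 5 of 15, Fos by -1.64 and Egr1 by -1.45. Ribosomal protein genes fell in 14 of 88, with Rps27l at -0.43 and Rps20 at -0.39. Of 13 matrix genes 2 rose and 4 fell, with Sparcl1 at -2.03 and Mmp14 at -1.25. Of 9 p53 targets 1 rose and 1 fell, Cdkn1a (-1.18), and Asah1 fell (-1.32) while Psap rose (0.74) among lysosomal genes, of which 4 of 23 rose. In the axon guidance list 3 of 15 rose and Jam3 fell (-0.80), and of 3 cytokine genes 1 rose and 1 fell, Mif (-0.64). Calls were lost in 10 of 21 alternatives for Asah1, 8 of 22 for Jam3, 5 of 22 for Hk2, 5 of 20 for Mmp14, 3 of 22 for Rps27l, 2 for Cdkn1a and 1 for Rps20 and Psap. Camera called none of these 8 lists, nor the growth factor list (2 higher and 4 lower of 10) or the 4 antigen presentation genes. The median and camera differed in sign for glycolysis (-0.02), cytokines (-0.22) and growth factors (-0.25), for which camera gave Up. Outside the lists, Dpysl3 (1.94 ± 0.20), a protein of growing axons, Rab6b (1.81) and Cadm3 (1.81) were the highest by the naming rule. The lowest were Kif4, a mitotic kinesin with 0 UMIs against 317 (at least 8.67-fold lower, but at -0.017 and not called with S and G2M scores regressed out), Gas6 (1 UMI, ratio 0.0288, interval 0.000728 to 0.161) and Gpc3 (1 UMI, ratio 0.0326, interval 0.000823 to 0.183).

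Vesicle genes changed in both directions. Of 98 EV genes tested 15 rose and 11 fell (16 and 13 when adjusted over the list alone). Flot1, a flotillin of membrane rafts, rose by 0.96 ± 0.26 (edgeR adjusted p = 0.00223), Chmp7, an ESCRT-III protein, by 0.93 ± 0.21 (0.000115), Chmp1a, of the same complex, by 0.60, and Rab7, a late endosome GTPase, by 0.58. The prion protein gene Prnp rose by 1.29 ± 0.22 (9.49e-08). Slc3a2, an amino acid transporter subunit, fell (-1.10 ± 0.15, 1.93e-11), as did Stx6 (-0.66) and Tspan3 (-0.33), all in 4 of 4 mice, as the naming rule required. Calls were lost in 13 of 22 alternatives for Tspan3, 10 for Chmp1a, 7 for Stx6, 6 for Rab7, 2 for Chmp7 and 1 for Prnp and Slc3a2, and in 3 of 21 for Flot1. The usual vesicle markers were not called: Cd63 was at 0.15 ± 0.10 (edgeR adjusted p = 0.328), Cd81 at 0.08 ± 0.11 (0.660), Cd9 at -0.23 ± 0.11 (0.154), Sdcbp (syntenin) at 0.26 ± 0.17 (0.327) and Pdcd6ip (ALIX) at -0.19 ± 0.30 (0.743). Cd63 reached the threshold in 5 of 22 alternatives and Cd81 in 2. Rab27a, a GTPase of vesicle release, had 8 UMIs in progenitor-like cells and 0 in the other classes and was not tested. None of the 4 EV lists was called by camera: ESCRT had 5 higher and 1 lower of 28 (adjusted p = 0.160), tetraspanins 2 and 2 of 16 (0.388, median -0.06 and mean 0.13), release 4 and 2 of 20 (0.671, median -0.11 though camera gave Up) and cargo 4 and 6 of 34 (0.897, median 0.07 and mean -0.09).

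Over all held-out genes, edgeR called 1185 of 7480 (483 higher, 702 lower). In simulated data for this comparison 50.4% of changes of 1 log2 unit and 87.7% of changes of 2 were recovered, and 3.92% of calls were false. The count was 781 without mouse 1 and 686 without mouse 4, and EV genes were 14 without either of them. It was 675 with S and G2M scores regressed out (14 EV genes), 527 with DESeq2 (12), 674 without the mouse block (12) and 482 with cells thinned to 2000 UMIs (9). Part of the granule-lineage-like cells, 22.6%, held under 30 Malat1 UMIs per 10000, and without them 373 genes were higher and 818 lower. The 2 differentiating clusters differed in this: 114 of the 336 cells formed a cluster with 21.8 Malat1 UMIs per 10000 and a median mitochondrial share of 6.07%, against 246 and 3.24% in the other.

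**Figure D2:**
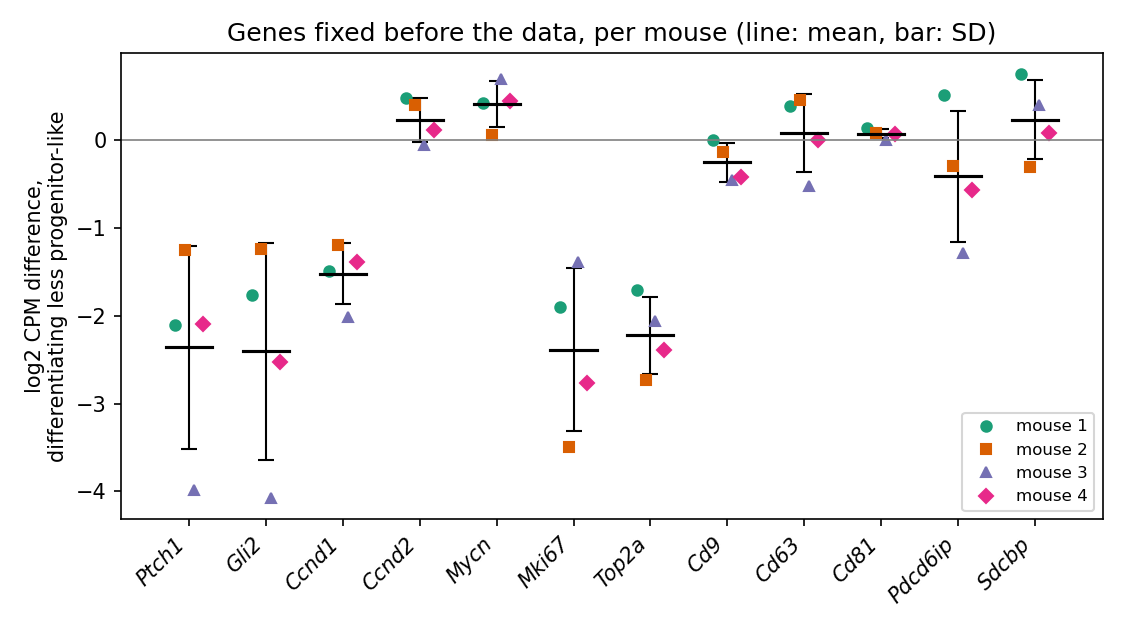
Log2 difference in CPM between differentiating and progenitor-like cells for 12 genes fixed before the data were examined, 1 point per mouse, with the mean as a line and the SD as a bar. Ptch1, Gli2, Ccnd1, Mki67 and Top2a lie below 0 in all 4 mice, while Cd63, Pdcd6ip and Sdcbp fall on both sides of it.

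The share of cells with a UMI of Mki67 or Top2a, thinned to 2000 UMIs per cell, was 44.5% ± 5.87 in progenitor-like and 17.5% ± 7.30 in differentiating cells (SD, n = 3), a difference of 27.0 ± 10.2 points in 3 of 3 mice. The exact two-sided sign-flip test gave p = 0.25, the smallest p that 3 mice allow, so no threshold could be passed. Mouse 3 had 4 differentiating cells of that depth and was left out, and its shares went the other way, with 3 of the 4 cells (75%) against 65.3% of progenitor-like cells. Below that depth were 1442 progenitor-like and 189 differentiating cells of the 4 mice. Unthinned shares were 42.9% ± 6.62 and 18.5% ± 4.27 (n = 4, exact p = 0.13, the smallest that 4 mice allow). Thinned to 1000 UMIs, they were 30.003% ± 4.33 and 7.26% ± 3.89 (n = 4, exact p = 0.13). Myeloid-like cells, taken as background, had such a UMI in 4 of 39 cells unthinned (10.3%, median depth 1236 UMIs against 1758.5 in differentiating cells), in 4 of 30 cells (13.3%) at 1000 UMIs and in 0 of 10 at 2000, which allows up to 30%. The differentiating share is therefore not told apart from background and is not read as division. With S and G2M scores regressed out before clustering, which draws other classes, the shares were 49.0% ± 11.5 and 48.1% ± 21.8. The difference was 0.953 ± 11.4 points (exact sign-flip p = 0.875, n = 4).

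Astroglia-like cells were compared with granule-lineage-like cells to describe the glia named in the design text. Matrix genes stood out: Sparc, a secreted collagen-binding protein, was higher by 4.54 ± 0.21 log2 units (SE, n = 4) and Serpine2, a protease inhibitor, by 4.39 ± 0.24. Ptn, a secreted growth factor of glia, was higher by 2.42 ± 0.16 (1126 ± 58.8 CPM, SD, against 213 ± 36.9). Ptch1 was lower by -1.37 ± 0.28 and Cdk6, a kinase of the G1 phase, by -0.96 ± 0.21. In edgeR the adjusted p was 7.49e-95 for Sparc, 6.89e-69 for Serpine2, 2.76e-48 for Ptn, 5.76e-05 for Ptch1 and 0.000494 for Cdk6. Each changed in the same direction in 4 of 4 mice, which was a condition of being named. In the matrix list 7 of 17 genes rose and none fell (camera adjusted p = 5.11e-12; adjusted p = 0.138 with an estimated correlation).

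Among vesicle genes 6 of 98 were called, all higher (7 higher and 2 lower when adjusted over the list alone). The direction moved with the processing: 7 rose and 5 fell with S and G2M scores regressed out, and 3 rose and 13 fell for the 1 cluster with the highest marker level, from at least 5 cells in each of 3 mice. Tspan7, a tetraspanin, was higher by 2.68 ± 0.31 (edgeR adjusted p = 4.26e-16) and Cd81 by 0.63 ± 0.16 (0.00491, 4 of 4 mice), a call lost without mouse 1, 2 or 4 (highest adjusted p over alternatives 0.181). The others were not called: Cd63 at -0.34 ± 0.17 (edgeR adjusted p = 0.337), Cd9 at -0.02 ± 0.18 (0.986), Sdcbp at 0.47 ± 0.27 (0.467) and Pdcd6ip at -0.62 ± 0.54 (0.689). The release list ranked above other genes with 1 of 20 called (camera adjusted p = 0.0373; adjusted p = 0.592 with an estimated correlation), while fry gave Down.

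Glycolysis rose in 3 of 16 genes (camera adjusted p = 0.000198; adjusted p = 0.345 with an estimated correlation), with Tpi1 at 1.11 ± 0.28 and Ldhb at 0.86 ± 0.19. S phase fell in 4 of 42 (camera adjusted p = 0.000216; adjusted p = 0.345 with an estimated correlation), with Dtl at -1.81 and Rpa2 at -1.53, and G2M in 10 of 51 (4.66e-05; adjusted p = 0.345 with an estimated correlation), with Cenpe at -1.82 and Aurka, a mitotic kinase with 3 UMIs, at a ratio of 0.193 (0.0397 to 0.568). Antigen presentation (1 of 3 genes higher, camera adjusted p = 0.0334), cytokines (1 of 4, 0.0312) and lysosome (1 of 22, 0.0412, fry Down), in which Psap rose by 0.82, were also called. Each had adjusted p = 0.345 with an estimated correlation. Ribosomal protein genes ranked above other genes (camera adjusted p = 0.000198; adjusted p = 0.647 with an estimated correlation) at a median of -0.01 over 88 genes, where the median of all genes was -0.18. Among lists that camera did not call, it gave Up at negative medians for tetraspanins (-0.13), cargo (-0.14) and axon guidance (-0.36). Without mouse 1 or mouse 4 it called 5 lists in place of 9. The immediate early genes Egr1 (-0.87) and Ier2 (-0.85) and the growth factor Pdgfa (-0.85) fell within lists that were not called, and Slc17a6 had 1 UMI (ratio 0.102, interval 0.00257 to 0.571). Calls were lost in 5 of 20 alternatives for Egr1 (-2.38 to -0.60) and Ier2, and in 8 of 20 for Pdgfa (-3.63 to -0.71) and Psap. Outside the lists Tsc22d4 (1.73), Glud1 (1.5), which makes glutamate dehydrogenase, and Gng12 (1.39) were higher, the last 2 with calls lost in 4 and 5 of 19 alternatives. Clock, Cntrl and Ppp1r10 had 1 UMI each, at ratios of 0.0888 (0.00224 to 0.498), 0.0834 (0.00211 to 0.467) and 0.0907 (0.00229 to 0.508). Among the genes of this paragraph with few UMIs, calls were lost in 10 of 18 alternatives for Slc17a6, 9 for Clock, 8 for Ppp1r10 and Aurka and 6 for Cntrl. They were also lost in 3 of 20 for Tpi1 and Rpa2, 2 for Ldhb and Cenpe and 1 for Dtl.

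Of 6299 held-out genes edgeR called 119 (58 higher, 61 lower), against 133 (73 and 60) with RLE size factors, which put the median of all genes at -0.11, and 72 (62 and 10) with DESeq2. The count was 67 without mouse 1, 57 without mouse 2 and 41 without mouse 4 (EV genes 3, 2 and 2), 69 without the mouse block, and 324 (20 higher, 304 lower, EV genes 3 and 13) for the 1 astroglia-like cluster with the highest marker level. That fit took mice with at least 5 of its cells, which left 10, 9 and 8 cells of mice 1, 2 and 4, and the median of all genes was -1.37. With S and G2M scores regressed out it was 230 (80 and 150, EV genes 7 and 5). Simulated changes of 1 and 2 log2 units were recovered in 24.5% and 62.7%. Granule-lineage and progenitor markers stood at 18.9 UMIs per 10000 in the astroglia-like cells, against 24.6 in progenitor-like and 8.04 in oligodendrocyte-lineage-like cells. The 3 astroglia-like clusters had median mitochondrial shares of 5.74, 3.93 and 5.70% and held 32.9, 82.0 and 167 Malat1 UMIs per 10000, against 2.96% and 150 in granule-lineage-like cells above the Malat1 limit.

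Oligodendrocyte-lineage-like cells were compared with granule-lineage-like cells in the same way. Cd9, a tetraspanin of vesicle membranes, was higher by 1.69 ± 0.18 log2 units (SE, n = 4), Cd81 by 1.14 ± 0.17 and Tspan7 by 2.70 ± 0.29, while Cd63, which marks late endosomes, was lower by -0.78 ± 0.18. Cd9 stood at 23.2 ± 10.7 UMIs per 10000 (SD) against 5.88 ± 0.531 in progenitor-like cells. Of 20 tetraspanins and flotillins 9 rose and 1 fell (camera adjusted p = 0.000161; adjusted p = 0.313 with an estimated correlation). In edgeR the adjusted p was 2.08e-19 for Cd9, 1.98e-09 for Cd81, 2.55e-18 for Tspan7 and 0.000240 for Cd63, each in the same direction in 4 of 4 mice. For Tspan7, not fixed beforehand, that agreement was a condition of being named. With equal cell numbers Cd63 was at -0.24 and not called (range over alternatives -0.87 to -0.24).

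The other EV lists were not called, with camera Up at negative medians for ESCRT (-0.24) and release (-0.07). In them Prnp rose (1.72 ± 0.29) and the ESCRT genes Vps37b (-1.43 ± 0.24) and Vps4b (-2.30 ± 0.60, 4 UMIs, all from mouse 2), the cargo gene Ezr (-1.99 ± 0.30), and the release genes Stx6 (-1.03) and Rala (-0.90) fell. Stx6, Rala and Vps4b lost their calls in 8 of 20, 10 of 20 and 3 of 18 alternatives. Sdcbp was at -0.32 ± 0.30 (edgeR adjusted p = 0.485) and Pdcd6ip at -0.62 ± 0.49 (0.392). Over 104 EV genes 16 rose and 16 fell, with the same count adjusted over the list alone. Of 16 growth factors 4 rose, Ptn among them (2.86 ± 0.18, edgeR adjusted p = 1.77e-54), and 5 fell, Fgf9 among them (-2.24). Of 4 cytokine genes 2 rose and 2 fell, Tgfb2 (-1.26) and Mif (-0.68). Camera called neither list. Of the SHH genes Boc, a co-receptor, was at -1.83 and Cdk6 at -1.90, in a list with 8 of 16 lower that camera did not call. Mif lost its call in 5 of 20 alternatives, Boc in 5 of 18, Fgf9 in 3 of 18 and Tgfb2 in 2 of 19.

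Matrix (13 higher and 2 lower of 18, camera adjusted p = 4.65e-14), axon guidance (11 and 2 of 22, 1.87e-07), lysosome (11 and 1 of 25, 1.87e-07), synapse (11 and 3 of 26, 6.93e-07) and antigen presentation genes (4 of 6 higher, 0.00894) ranked above other genes. With an estimated correlation these had adjusted p = 0.141, 0.313, 0.313, 0.273 and 0.337 in that order. S phase (27 of 41 lower, camera adjusted p = 1.04e-08), G2M (29 of 52 lower, 1.87e-07) and ribosomal protein genes (78 lower and 1 higher of 89, 3.53e-10) ranked below. Those had adjusted p = 0.273, 0.348 and 0.395 with an estimated correlation. In glycolysis (-0.16), immediate early genes (-0.31) and p53 targets (-0.06), not called, camera gave Up at a negative median. The precursor-like cluster held 743.5 Malat1 UMIs per 10000 and a median of 6.78% mitochondrial UMIs, against 150 and 2.96% in granule-lineage-like cells above the Malat1 limit.

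Of 6755 held-out genes edgeR called 1450 (480 higher, 970 lower). RLE size factors gave 577 higher and 737 lower, with EV genes at 18 and 12 and the median of all genes at -0.05 in place of -0.18, and DESeq2 gave 453 and 365, with EV genes at 15 and 8. The count was 853 without mouse 2 (22 EV genes) and 460 with equal cell numbers (19). In simulated data 7.04% of calls were false, and 20.4% and 66.5% of changes of 1 and 2 log2 units were recovered. The simulation held no shift of most genes, so this false rate does not cover the move of directions between size factors.

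**Figure D3:**
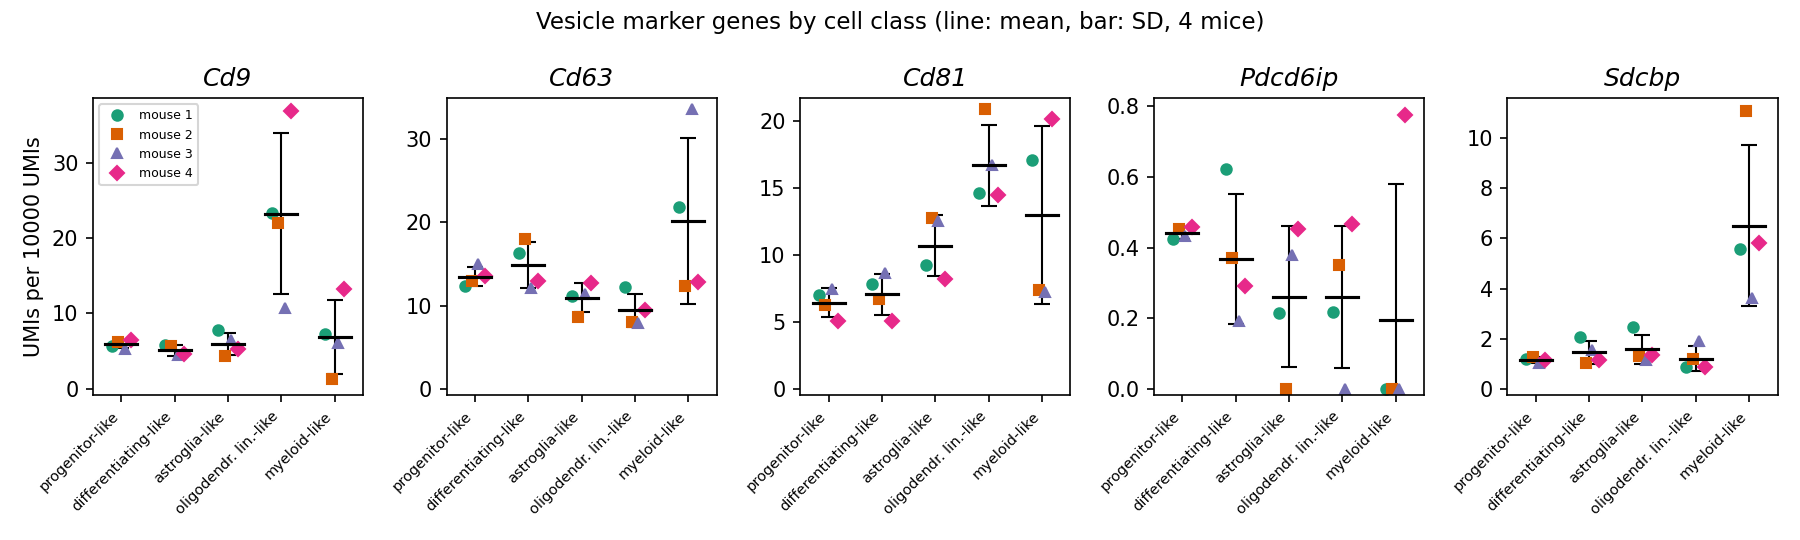
UMIs per 10000 UMIs of 5 vesicle marker genes in 5 cell classes, 1 point per mouse, with the mean as a line and the SD as a bar over 4 mice. Cd9 and Cd81 are highest on average in oligodendrocyte-lineage-like cells (23.2 and 16.7) and Cd63 and Sdcbp in myeloid-like cells (20.1 and 6.52), where the SD is 10.0 and 3.20.

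Myeloid-like cells were compared with granule-lineage-like cells, to describe the immune cells named in the design text, from 39 cells. They carried the transcripts of antigen presentation and the lysosome: B2m, the light chain of class I molecules, was higher by 4.83 ± 0.29 log2 units (SE, n = 4) and H2-D1, a heavy chain, by 3.94 ± 0.38. Ctss, a lysosomal protease of microglia, had 217 UMIs against 3, and Laptm5, a lysosomal membrane protein of blood cells, 64 against 0 (at least 3074-fold higher). Of the vesicle genes Sdcbp, which works with ALIX in exosome budding, was higher by 1.82 ± 0.40, and Tspan4 by 3.29 ± 0.54. In edgeR the adjusted p was 4.21e-59 for B2m, 5.25e-23 for H2-D1, 0.000106 for Sdcbp and 4.71e-08 for Tspan4, each higher in 4 of 4 mice. For B2m, H2-D1 and Tspan4, not fixed beforehand, that agreement was a condition of being named.

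Of 28 lysosomal genes 19 rose and 1 fell (camera adjusted p = 8.43e-46), with 8 of 10 antigen presentation genes higher (2.96e-16) and 6 higher and 2 lower of 8 cytokines (8.84e-08). Each of these 3 lists had adjusted p = 0.248 with an estimated correlation, and fry gave Down for the cytokines. Immediate early genes rose in 10 of 18 (camera adjusted p = 1.23e-10; adjusted p = 0.311 with an estimated correlation), Junb by 4.27 ± 0.42 and Klf6 by 3.37 ± 0.48. Junb stood at 1144 ± 1459 CPM, an SD above the mean. All cells were dissociated for 20 minutes and sorted before capture. The level of immediate early genes in the intact tumour was therefore not measured, and handling cannot be told apart from the state of these cells. Sparc (4.04), Ldhb (1.08) and, outside the lists, the interferon gamma receptor genes Ifngr1 (3.15) and Ifngr2 (3.14) and Aup1 (2.37) were also higher, with calls lost in 3 of 18 alternatives for Ldhb, 2 of 17 for Aup1 and, above, 1 of 17 for Klf6. The ratio of Ctss was 10424 (interval 3520 to 50941).

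Of 100 EV genes 9 rose and 15 fell (10 and 17 when adjusted over the list alone). RLE gave 14 higher and 10 lower and DESeq2 11 and 6. Cargo genes ranked above other genes (camera adjusted p = 3.16e-05; adjusted p = 0.366 with an estimated correlation) with 6 higher and 10 lower of 38, a median of -0.42 and fry Down. Tetraspanins did too (adjusted p = 0.0154; adjusted p = 0.399 with an estimated correlation) with 2 and 2 of 17, a median of -0.12 and fry Down. Ezr had 3 UMIs (ratio 0.165, interval 0.0340 to 0.483) and Smpd2 1 (0.133, 0.00335 to 0.740). Ywhaq (-3.17 ± 0.49) and Vps37b (-2.76 ± 0.55) fell, and Tspan6 and Cttn had 0 UMIs (at least 2.94-fold and 1.60-fold lower). Cttn, Smpd2 and Ezr lost their calls in 6 of 16, 5 of 16 and 1 of 17 alternatives. Cd63 was at -0.12 ± 0.27 (edgeR adjusted p = 0.766), Cd81 at 0.54 ± 0.30 (0.184) and Cd9 at -0.18 ± 0.33 (0.707), and Pdcd6ip had 2 UMIs. The direction of Cd63 turned with the fit: 0.67 with all classes in one fit and 0.64 with equal cell numbers. Cd81 was called in 6 of 18 alternatives (0.06 to 1.56, smallest edgeR adjusted p 1.35e-05) and Cd9 in none (-0.68 to 0.70). By UMIs alone the ratios of Cd63, Cd81 and Cd9 were 1.39 (interval 1.15 to 1.66), 2.52 (2.06 to 3.06) and 1.47 (1.11 to 1.91), against a median of -1.18 over all genes in the fit.

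The proliferation genes Mki67, Aurkb, Dtl and Mcm2 had 0 myeloid-like UMIs (at least 4.65-, 2.12-, 3.58- and 2.57-fold lower). S phase fell in 18 of 41 (camera adjusted p = 0.00411; adjusted p = 0.311 with an estimated correlation) and G2M in 25 of 51 (0.00158; adjusted p = 0.399 with an estimated correlation), at medians of -2.67 and -2.66, or -1.98 and -1.92 with genes at 0 set to their bound. Nkd1, Cacng2 and Ezh2 had 0 UMIs (at least 5.63-, 5.14- and 4.97-fold lower), as did Tgfb2 (2.85), Jam3 (1.88), Boc (1.61), Sparcl1 (1.34) and Robo2 (1.32). Mdk had 1 UMI (ratio 0.0544, interval 0.00138 to 0.303), as did Ptn (0.0753, 0.00190 to 0.420), Hk2 (0.157, 0.00397 to 0.878) and Cacna2d1 (0.171, 0.00433 to 0.956), and Cdk6 had 3 (0.10, 0.0207 to 0.294). Rpl4 (-1.37), Rps4x (-1.33) and Mif (-1.05) fell in a fit whose median over all genes was -1.18, and lost their calls in 1, 3 and 5 of 18 alternatives. Their ratios of UMIs were 0.581 (0.483 to 0.694), 0.670 (0.576 to 0.776) and 0.725 (0.540 to 0.955). Of the genes with 0 or 1 UMI, calls were lost in 10 of 17 alternatives for Sparcl1, and of 16 in 9 for Cacna2d1, 8 for Hk2, 7 for Robo2, 6 for Boc and 3 for Jam3 and Aurkb. Axon guidance (3 of 11 lower) was called Down (camera adjusted p = 0.00454; adjusted p = 0.359 with an estimated correlation). Of its genes 7 had 0 myeloid-like UMIs, so its median of -7.37 rests on fitted values and is known only to be at most 0.65. Glycolysis (adjusted p = 0.0307; adjusted p = 0.311 with an estimated correlation) and matrix (0.0179; adjusted p = 0.366 with an estimated correlation) were called Up by camera at medians of -0.44 and -0.46, with fry Down. With genes at 0 set to their bound, glycolysis stayed negative (-0.35), while for matrix (1.18), tetraspanins (0.09), p53 targets (0.21) and the uncalled growth factors (0.24, fitted -4.45) the sign of the median is left open. Camera also gave Up, uncalled, at negative medians for ESCRT (-1.03), release (-0.79), synapse (-1.33), p53 targets (-0.20) and ribosomal protein genes (-0.76).

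Of 5927 held-out genes edgeR called 1017 (153 higher, 864 lower), and 444 of the 864 had at most 3 myeloid-like UMIs. RLE gave 541 (203 and 338), DESeq2 318 (203 and 115) and equal cell numbers 168 (82 and 86), with the median of all genes at -1.18 in the edgeR fit, -0.69 with RLE and -0.49 with DESeq2. The counts were 408, 607, 592 and 404 without mice 1 to 4. In simulated data, which held no shift of most genes, 19.0% of edgeR's calls were false, against 0.662% with DESeq2. These rates do not cover the effect of the size factors on the real calls. Changes of 1 and 2 log2 units were recovered in 4.90% and 25.9% with edgeR, so a gene not called here may still have changed.

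Myeloid-like cells were also set against astroglia-like cells (39 against 136 cells). Cd63 was higher in myeloid-like cells by 0.98 ± 0.21 log2 units (SE, n = 4), Sdcbp by 2.19 ± 0.44, and Clic1, a chloride channel protein found in vesicles, by 2.76 ± 0.47. Without a UMI in astroglia-like cells were Lgals3 (galectin-3, 46 UMIs, at least 64.5-fold higher), Spp1 (osteopontin, 39, at least 54.7-fold), Igf1 (35, at least 49.0-fold) and the leukocyte tetraspanin Cd53 (32, at least 44.8-fold). Ptn had 1 UMI against 301 (ratio 0.0140, interval 0.000352 to 0.0784) and Ccnd2 fell by -1.87 ± 0.43. In edgeR the adjusted p was 0.000324 for Cd63, 0.000168 for Sdcbp, 2.18e-05 for Clic1 and 0.000777 for Ccnd2, each in the same direction in 4 of 4 mice. For Clic1 and Ccnd2, not fixed beforehand here, that agreement was a condition of being named.

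Cd81 was called at 0.77 ± 0.28 (edgeR adjusted p = 0.0257) but was higher in 2 of 4 mice and lost its call in 6 of 17 alternatives, and Cd9 was at 0.60 ± 0.34 (0.152). Lysosomal genes rose in 12 of 13 (camera adjusted p = 1.64e-12; adjusted p = 0.136 with an estimated correlation), antigen presentation in 4 of 4 (4.69e-05; adjusted p = 0.136 with an estimated correlation) and immediate early genes in 7 of 7 (0.0238; adjusted p = 0.443 with an estimated correlation). Of 23 EV genes 10 rose and 5 fell, with the same count adjusted over the list alone. Camera called neither the tetraspanin list (5 genes) nor the cargo list (17). The ESCRT list, with 1 gene, and the release list, with no gene left, were not tested by camera. Matrix genes, not called, had a median of 0.14 and a mean of -2.34 over 3 genes. Of 471 held-out genes edgeR called 167 (84 higher, 83 lower), 95 without mouse 1 (10 EV genes), 102 without the mouse block and 374 without the low-count filter (85 higher, 289 lower, EV genes 9 and 12 of 120), when Cd63 lost its call (adjusted p = 0.660). Sums of few UMIs left 606 genes to test. In simulated sets, which tested 439.6 genes on average, 71.9% of changes of 1 log2 unit were recovered.

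In GRCm38 coordinates the genes named most often are protein-coding: Cd9 lies on chromosome 6 at 125460266 to 125494791, Cd63 on chromosome 10 at 128900989 to 128912822, Cd81 on chromosome 7 at 143052739 to 143067934, and Sdcbp on chromosome 4 at 6365650 to 6408423. Ptch1 lies on chromosome 13 at 63508328 to 63573598 and Ptn on chromosome 6 at 36714929 to 36810220.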

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

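Of 172 sets of 4 mice examined, 14 had 1 mouse far from the other 3, with a gap to the nearest that takes more of the whole range than the 95% limit of Dixon's test, where chance flags about 1 in 20 sets. All 14 are differences of 1 gene between classes of cells, on the log2 scale per mouse, and no explanation was tested for them.

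In differentiating against progenitor-like cells, Chmp1a was at 0.32 in mouse 3 and at 0.61, 0.62 and 0.67 in the others. Slc17a6 was at 2.72 in mouse 1, against 1.23, 1.47 and 1.48. In astroglia-like cells Cenpe was at -6.28 in mouse 2, against -1.64, -1.55 and -1.39, and Cntrl at -1.67 in mouse 1, against -5.01, -4.95 and -4.57. In oligodendrocyte-lineage-like cells Vps4b was at -0.48 in mouse 2, against -5.37, -5.14 and -5.11, so all its UMIs in the class come from that mouse.

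In myeloid-like against granule-lineage-like cells, Pdcd6ip was at 0.52 in mouse 4 (others -4.78, -4.76 and -4.70) and B2m at 4.05 in mouse 2 (others 4.95, 5.02 and 5.12). Smpd2 was at -2.09 in mouse 1 (others -6.24, -5.79 and -5.54), Mdk at -2.12 in mouse 3 (others -7.51, -7.39 and -7.32) and Ptn at -2.81 in mouse 4 (others -7.06, -6.87 and -6.56). Rpl4 was at -2.27 in mouse 2 (others -1.27, -1.12 and -1.10) and Cacna2d1 at -1.51 in mouse 4 (others -6.07, -5.73 and -5.50). Against astroglia-like cells Cd53 was at 1.89 in mouse 3 (others 3.65, 3.92 and 3.93) and Igf1 at 3.27 in mouse 2 (others 3.87, 3.92 and 3.93). Several of these genes rest on 1 to 4 UMIs in the smaller class, in which a mouse without a UMI takes a value set by the prior count.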

How the results depend on the processing

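Alternatives without low-Malat1 cells, without Xist-positive cells, with the unnamed cluster as progenitor-like, with 1 astroglia-like cluster, and all myeloid fits were chosen after seeing the data. Of 300 summary values under an alternative 225 stayed within 1.5 times the count or 1 SD and 75 moved, and for named genes and lists 4 values reversed, 378 lost a call, 35 gained one and 2911 did neither. Named genes that kept their call in every alternative run were 19 of 43 for differentiating cells, 6 of 24 for astroglia-like, 8 of 16 for oligodendrocyte-lineage-like, 23 of 39 for myeloid-like and 8 of 10 for myeloid-like against astroglia-like cells. Some alternatives repeat another fit and still count in these tallies. At least 20 cells per class repeats the main fit for differentiating cells and the fit without mouse 3 for astroglia-like cells. Below, counts are held-out genes, EV genes follow in brackets, and where nothing is said the cause was not tested.

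Class shares moved with the clustering. At Leiden resolution 2 progenitor-like cells were 67.8%, differentiating 14.6% and unnamed 9.49%, at 0.5 differentiating 13.2% and unnamed 0%. With S and G2M scores regressed out they were 73.5% and 13.8%. With listed genes among the clustering genes differentiating cells were 10.6% and unnamed 0%, with 1000 clustering genes differentiating 11.02% and oligodendrocyte-lineage-like 4.92%, and without doublet removal unnamed 0%. The strict filter (at least 1000 genes, at most 5% mitochondrial) gave differentiating 15.5%, astroglia-like 0.591% and myeloid-like 0.262%.

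For differentiating cells, S and G2M regression gave 675 (14), with Mki67 at 0.016 and Cdca2 at 0.12 in place of negative values, and the strict filter (12). DESeq2 gave 527 (12), all classes in one fit 616, thinning to 2000 UMIs 482 (9), with fewer UMIs by construction, and equal cell numbers 663. For astroglia-like cells, S and G2M regression gave 230 (12, 5 of them lower), DESeq2 72, all classes in one fit (3), no low-count filter (3), with more genes tested, and the cluster of the highest marker level, with at least 5 cells in 3 mice, 324 (16, 13 of them lower), against 6 EV genes, all higher. For oligodendrocyte-lineage-like cells, resolution 2 gave 944, 1000 clustering genes 773, DESeq2 818, all classes in one fit 762 (21) and equal cell numbers 460 (19), with fewer cells. For myeloid-like cells, RLE gave 541, DESeq2 318, all classes in one fit 445 with Cd63 reversed at 0.67 (adjusted p = 0.00719), and equal cell numbers 168 (14) with Cd63 at 0.64 (adjusted p = 0.0162). The adjusted p of Cd63 ran from 0.00719 to 0.983 over its alternatives. For myeloid-like against astroglia-like cells, DESeq2 gave 108, all classes in one fit 324, equal cell numbers 94 and no low-count filter 374. With an estimated correlation camera called 0 lists in each of the 5 comparisons, against 4, 9, 9, 11 and 3.

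Without the replicate block that pairs classes of a mouse, counts were 674 (12) for differentiating cells, 69 for astroglia-like cells and 102, with 1 list, for myeloid-like against astroglia-like cells. No other summary moved.

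Leaving out each mouse, counts ran from 686 to 1215 (14 to 27, lists 4 to 6) for differentiating cells, 41 to 135 (2 to 7, lists 5 to 9) for astroglia-like, 853 to 1193 (22 to 31, lists 8 to 10) for oligodendrocyte-lineage-like, 404 to 607 (17 to 24, lists 9 to 13) for myeloid-like and 95 to 177 (10 to 17, lists 2 to 4) for myeloid-like against astroglia-like cells. These fits hold 3 mice in place of 4, and for all comparisons but myeloid-like against granule-lineage-like cells the highest count came without mouse 3. Shares ran from 78.4 to 83.3% for progenitor-like, 6.84 to 8.82% for differentiating, 2.75 to 3.62% for astroglia-like, 3.00 to 3.88% for oligodendrocyte-lineage-like, 0.830 to 0.974% for myeloid-like and 2.93 to 4.25% for unnamed cells. The main Mki67 or Top2a difference of 27.0 points already leaves out mouse 3, so the fit without mouse 3 repeats it. It could not be had without another mouse.

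Not run for lack of cells were the strict filter and thinning for the 4 comparisons with non-granule cells, 20 cells per class for both myeloid ones, the removal of low-Malat1 cells for astroglia-like and both myeloid ones, and the planned myeloid and vascular comparisons.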

Other observations

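The tests of the depth of low-Malat1 cells, and every test of Xist-positive cells and of granule markers in astroglia-like cells, were chosen after the result was seen, and the 2 tests of nuclear transcripts and the splits before it.

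A UMI of Mki67 or Top2a was found in 24 of 102 astroglia-like cells thinned to 1000 UMIs (23.5%, exact Clopper-Pearson 95% interval 15.7 to 33.0%), in 15 of 113 oligodendrocyte-lineage-like cells (13.3%, 7.62 to 20.9%) and in 4 of 30 myeloid-like cells (13.3%, 3.76 to 30.7%). The last interval covers the other 2 shares, but also the 29.7% of progenitor-like cells (860 of 2893). With so few myeloid-like cells as background, the comparison cannot decide whether any of these classes divides. The 23 oligodendrocyte-like cells were 1.79% of cells in mouse 4 (1.11 to 2.73%) and 0 of 704 in mouse 3. The choroid-plexus-like cells, led by Ttr, were 5 cells.

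A part of the granule-lineage-like cells, 826 of 3652, held few Malat1 UMIs: 8.99 per 10000 against 150 in the others, with a share of 9.23 to 31.0% over mice. Their Kcnq1ot1 (0.267 against 2.83) and Ptch1 (0.671 against 2.91) were lower and their mitochondrial share was higher (4.11% against 2.96%). Shallow depth is argued against, since 0.876% of 2627 other cells thinned to 1000 UMIs fell under the limit, against 22.6% measured. Droplets that lack nuclear RNA cannot be told apart: other long noncoding RNAs were not lower than protein-coding genes (median difference over mice 0.13, range 0.04 to 0.52), but the bound set beforehand was wrong, since the list left out Malat1, Kcnq1ot1 and Miat (0.146 against 1.08), already seen low. A loss of transcripts held in the nucleus cannot be told apart either, because Meg3, Pvt1 and Airn had a median of -0.77 (-0.98 to 0.28) from few UMIs. Left out of that median for too few counts were Neat1 (0 UMIs against 38), Snhg11 (0 against 7) and Mirg (0 against 3). No biological explanation was tested, since the series has 1 group.

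In the libraries of mice 2 and 4, whose other cells hold Y-linked transcripts (289 and 411 cells), 32 and 129 cells held Xist and no Y-linked UMI. Barcodes shared with the libraries of mice 1 and 3 are argued against (1 of 161 cells), and so is free Xist RNA, since 3.52% of Y-linked cells of mouse 4 held Xist against 17.3% of its other cells. Outside the X and Y chromosomes, the Xist-positive cells of mouse 4 lay 0.664 of the way from its Y-linked cells to the cells of mouse 3 (95% interval 0.618 to 0.737, 111 cells), so cells of mouse 3 in that library are a candidate explanation. For mouse 2 and mouse 1 the value was 0.217 (0.0329 to 0.346, 27 cells), which cannot be told apart with so few cells. Without these cells the counts of held-out genes were 1167, 128, 1435, 1017 and 155 for the 5 comparisons, and no biological explanation was tested.

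Granule-lineage and progenitor markers, summed, stood in astroglia-like cells at 2.34 times their level in oligodendrocyte-lineage-like cells. The 95% counting interval on pooled UMIs, 2.01 to 2.74, leaves out the spread between mice. By mouse the ratio ran from 1.38 to 4.30, above 1 in each, and was lowest in mouse 3, from 46 marker UMIs in each class. This argues against free RNA as the only source of the sum. A sum cannot tell free RNA of some markers from the cells' own expression of others, and single markers were not tested. Doublets are argued against for the 2 shallower clusters, whose median UMIs were 0.558 of those of granule-lineage-like cells (0.390 to 1.02 over mice, 85 cells). For the deepest cluster the ratio was 0.891 (0.540 to 1.39, 51 cells), and doublets cannot be told apart there because the mice lie on both sides of 1. Granule-lineage-like cells mixed into these clusters cannot be told apart either, since the odds ratio between both marker sets within cells was 0.720 (0.309 to 1.68, 102 cells). No biological explanation was tested, and cells that carry both programs remain open.

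The 8 sums of each comparison, 4 mice and 2 classes, can be split in 35 ways, and in each comparison 1 of the 35 splits, the real one, gave as many held-out and EV genes. The classes were clusters of these same cells, which puts the real split first by design, so the splits leave open whether chance made the classes. Fitted without the mouse block, the real and the highest other count were 674 and 3 for differentiating, 69 and 5 for astroglia-like, 1004 and 3 for oligodendrocyte-lineage-like, 1058 and 10 for myeloid-like, and 102 and 0 for myeloid-like against astroglia-like cells. For EV genes they were 12 and 0, 4 and 0, 25 and 0, 28 and 1, and 11 and 0. Of the 8 ways to swap classes within mice, with the block kept, the highest other count was 6, 8, 9, 40 and 0 in the same order, against 1185, 119, 1450, 1017 and 167, and 8 ways are too few for a share under 0.05.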
